A study of Homo sapiens with 18 samples.

How the data were processed

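The data are mRNA profiles of Raji cells, an established human B-cell line from a Burkitt lymphoma, measured on 18 Affymetrix gene expression arrays with 1 value per probe set. Per the labels, cells received sodium n-butyrate (3 mM), a phorbol ester (0.05 µM) and maslinic acid (19 µM) and were harvested at 0, 4, 8, 12, 24 or 48 h, with 3 arrays per time that the labels call biological replicates. Per the labels' protocols, total RNA was purified on columns and biotinylated cDNA was made from it by the array maker's standard method. The deposited values are log2 intensities. The log base was deduced from the range of the values, because a maximum near 13 in another base would exceed what the scanner can record. The authors normalized the values between arrays and did not centre them per gene. The software, background correction, normalization method and annotation build were not given in the sources used here, and the values were used as deposited.

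The 18 array medians lay between 4.03 and 4.25 and the maxima between 12.39 and 12.93 on the log2 scale, and no 2 arrays held identical values. The interquartile range was 2.74 to 3.16 on 17 arrays and 2.37 on replicate 2 of 8 h. For arrays, only their number limits the precision that could be stated, since no counts stand behind a value. Genes whose values lie near the lower end of the scale can hide changes under the background signal. Where a difference or fold is given as "at least", the earlier level was near background, which can make the estimate too small. The spread between arrays is not covered by that wording.

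The table held 33297 probe sets. A gene table supplied with the platform named exactly 1 gene for 19460 of them and several genes for 1754, and 12083 were not named here. Of the 1-gene probe sets, 19429 matched the reference gene table by gene ID and 0 symbols needed updating. Each of 18417 genes was represented by the probe set with the highest mean over all arrays, a choice that mattered for the 769 genes with more than 1 probe set. Among the named genes, second probe sets of lower level differed far less from 0 h for PCLAF at 24 h (-0.75 against -2.77), BIRC5 at 48 h (-1.46 against -3.90), ACKR4 at 8 h (-0.22 against -2.62), TUBB2A at 4 h (0.49 against 1.94) and ZNF75A at 4 h (1.09 against 1.89), and for KRT18 at 4 h the sign differed (-0.16 against 0.50). No filter on dim genes was applied and no coordinates were used.

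Arrays were grouped by harvest time. A linear model with group as the only term was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation (12 residual and 5.58 prior degrees of freedom). The moderated F test asked which genes differed from 0 h at any time. Moderated two-sided tests compared each later time with 0 h and each time with the one before it, and p-values were adjusted by the Benjamini-Hochberg method within each comparison. A gene counted as changed at an adjusted p under 0.05, and the subset with at least a 2-fold change was counted too. Values in the text are means ± SD of 3 arrays, and differences are on the log2 scale with the standard error (SE) of the model. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots.

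The 29 gene lists cover signalling and stress pathways, the cell cycle, B cell and plasma cell genes, and markers of T cells, monocytes, epithelium, fibroblasts and erythroid cells. They hold 588 genes, of which 540 were measured and the others were not analysed here. Each list was tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted over the lists and the 5 times against 0 h, and separately over the lists and the 4 consecutive comparisons. Camera compares a list with the remaining genes. The same test with a correlation estimated from the data and fry were run as alternatives, and fry asks only whether a list's genes move one way on balance. Members past the test were counted after adjustment over all genes and adjusted over the list alone. In 38 of 261 list results the median, the mean and the test differed in sign, and 0 of these were called.

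The tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 10 largest rises and falls at each time against 0 h, the 5 largest of each between consecutive times, both among genes past the test whose 3 arrays all lay on 1 side of the 3 arrays compared, and up to 4 members of each list with the largest difference from 0 h among those past the F test. Where fewer than 2 members passed, those of smallest p were given as values. Unnamed loci, small and antisense RNAs and sex chromosome markers were counted but not named. List members given to spell out a count of 5 or fewer, and further members whose choice is stated, were chosen after their values were seen.

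The alternatives were quantile normalization, centring each array on its median, leaving out the dimmest genes by mean, the mean of all probe sets of a gene, all probe sets tested singly, a trended and robust prior, array weights, the replicate number as a block, only the 2 groups compared in the fit, and leaving out each array in turn. A covariate for each array's interquartile range and the removal of replicate 2 of 8 h from every fit were added after the data were seen. The pipeline was tested on simulated data with the design of 4 h against 0 h over 18417 genes, 40 changed genes per size. It recovered 7.5% of genes changed by 0.5 on the log2 scale, 70% at 1, 90% at 1.5, 97.5% at 2 and 100% at 3, and 4 of 150 calls were false. In the same simulation 10 of 146 calls of the F test were false, or 6.85%, above the 5% aimed at. The simulated genes were drawn independently of each other, so the simulations cannot test how correlation between genes affects the list calls. A simulated rise of 0.5 over 1 list at 4 h was called against 0 h. Over all other lists and comparisons there was 1 further call. It can be the same list at 8 h against 4 h, a true difference, so it was not counted as false.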

Results

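The series followed mRNA levels over time in Raji cells, an Epstein-Barr virus-positive B-cell line, under 3 compounds given together. Sodium n-butyrate inhibits histone deacetylases, phorbol ester activates protein kinase C, and the pair is used to induce the viral lytic cycle in such lines. Maslinic acid is a pentacyclic triterpene from plants such as the olive. Cells were harvested at 0, 4, 8, 12, 24 and 48 h, and 3 biological replicates per time gave 18 arrays and 18417 measured human genes. All arrays carry the same treatment in the labels, the 0 h arrays included, so each comparison below is one of times under all 3 compounds. An arm without maslinic acid or without the inducers was not analysed here, so no difference can be assigned to 1 compound. Untreated arrays of the later times were not analysed here either. Effects of the compounds together therefore cannot be told apart from those of time in culture.

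Across the time course, the early response gene EGR1 rose by 4 h and the complement receptor gene CR2 fell by 8 h. The interferon-stimulated gene IFIT1 rose between 12 h and 24 h, and the cell division gene BIRC5 fell at 24 h and again between 24 h and 48 h. The moderated F test called 3023 of 18417 genes (16.4%) as different from 0 h at some time. Among these, the largest difference from 0 h came at 48 h for 501 genes that were higher and 817 that were lower, and at 24 h for 547 and 193. It came at 4 h for 119 and 78. The number of changed genes was 322 at 4 h, 1230 at 8 h, 1483 at 12 h, 2298 at 24 h and 2768 at 48 h. With array weights the F test called 5422 genes. The weights were 5.184, 0.246 and 0.827 for replicates 1 to 3 of 8 h, so the weighted 8 h values rested mostly on 1 array.

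**Figure D1:**
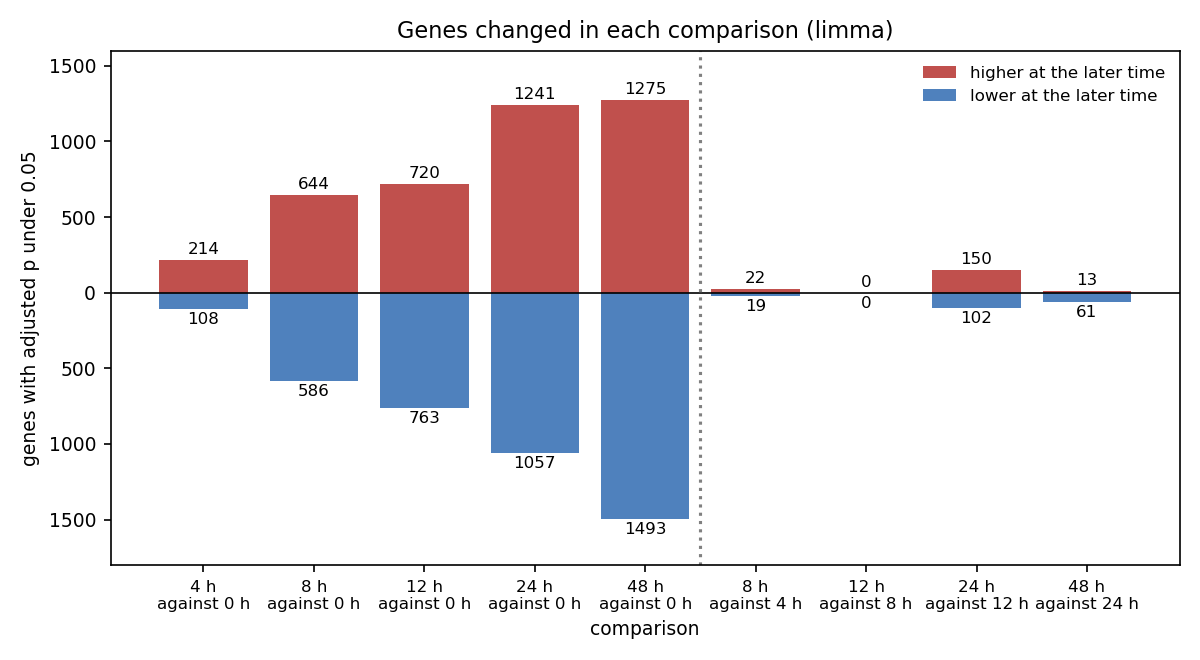
Number of genes with an adjusted p under 0.05 (limma) in each of 9 comparisons of harvest times, with genes higher at the later time drawn upward and genes lower drawn downward from 0. Against 0 h the bars grow from 214 higher and 108 lower at 4 h to 1275 and 1493 at 48 h, and 12 h against 8 h has 0.

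At 4 h the immediate early transcription factor EGR1 was 14.8-fold above 0 h, at 10.19 ± 0.19 against 6.30 ± 0.59 (SD, n = 3 each), a log2 difference of 3.88 (SE 0.33, adjusted p = 1.88e-05). CCR7, the receptor that guides lymphocytes to lymph nodes, rose 10.8-fold, from a 0 h level with an SD of 1.66 (adjusted p = 0.00579). The inflammatory cytokine TNF rose by 1.93 on the log2 scale, the glucose transporter SLC2A3 by 2.32, the tubulin gene TUBB2A by 1.94 and the lymphocyte receptor SLAMF7 by 1.91. ZSWIM6, ZNF597, ZNF75A and the pseudogene PRKXP1 completed the 10 largest rises, at 1.88 to 2.14. MYC, the growth-promoting transcription factor whose translocation marks Burkitt lymphoma, fell by 1.40 on the log2 scale, from 6.40 ± 0.46 to 5.01 ± 0.18 (SD, n = 3 each, adjusted p = 0.0016). TASL, an adaptor of Toll-like receptor signalling, fell by 1.78, the GTPase gene RHOH of blood cells by 1.64, and the lymphoid transcription factor IKZF3 and the lectin-like gene CLECL1 by 1.36 each. MMAA and ZNF33A fell by 1.57, ZFP62 by 1.52, COIL by 1.33 and TAS2R46 by a log2 difference of -1.30.

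Of the 24 immediate early and AP-1 genes, 6 rose at 4 h (8 adjusted over the list alone), with a list median of 0.31 (adjusted p = 0.225 with an estimated correlation). Within the BCL2 family and caspases, which set the threshold for apoptosis, 2 of 24 genes rose (4 adjusted over the list alone), MCL1 and APAF1, the latter by 1.64. That list had an adjusted p = 0.347 with an estimated correlation. INSIG1 and SC5D, of cholesterol synthesis and uptake, were the 2 of 18 members that rose (4 adjusted over the list alone; adjusted p = 0.444 with an estimated correlation). TNFAIP3 and CD83 were the 2 of 22 NF-kappaB target genes that rose (3 adjusted over the list alone; adjusted p = 0.5 with an estimated correlation). The lysosomal hydrolase GLA alone rose among 22 autophagy and lysosome genes, by 1.08 (4 rose adjusted over the list alone; adjusted p = 0.444 with an estimated correlation). Camera called 11 of the 29 lists at 4 h, 7 upward and 4 downward. With an estimated correlation 0 of these calls held, and their adjusted p ran from 0.225 to 0.589.

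Limma called 322 of 18417 genes at 4 h against 0 h, 214 higher and 108 lower, of which 123 and 50 differed at least 2-fold. The count was 135 without replicate 2 of 0 h, 156 without replicate 1 of 4 h and 109 without replicate 2 of 4 h. It was 125 when the fit held only the 6 arrays compared, 526 with the interquartile range as a covariate and 566 with array weights. The share of higher genes was 66.5% as deposited and 53.2% with each array centred on its median. The call of SLC2A3 was lost without replicate 2 of 0 h (adjusted p = 0.0635). Those of SLAMF7, IKZF3 and COIL were lost without replicate 2 of 4 h (adjusted p = 0.0686, 0.108 and 0.145). PRKXP1, MMAA and GLA lost theirs without replicate 3 of 0 h (adjusted p = 0.103, 0.123 and 0.176). TAS2R46 lost its call whichever of the 6 arrays was left out (adjusted p from 0.0533 to 0.107). The alternatives for each gene numbered 15, each array left out counted singly. Under 8 of them GLA lost its call, under 6 PRKXP1 and under 5 each IKZF3, COIL and MMAA. The call of CCR7 was lost in the fit of the 6 arrays alone (adjusted p = 0.0647).

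At 8 h CR2, the complement receptor through which Epstein-Barr virus enters B cells, was at 5.45 ± 0.65 against 8.14 ± 0.82 before (SD, n = 3 each), 6.42-fold lower (adjusted p = 0.000586). The germinal centre gene GCSAM fell by 2.55 on the log2 scale, RHOH by 2.56, the lectin receptor CLEC2D by 2.44, IKZF3 by 2.34 and the SLAM-family receptor CD84 by 2.27. RASSF6, the decoy chemokine receptor ACKR4, CLECL1 and CYTIP fell by 2.26 to 2.71. Higher at 8 h were CCR7 by 3.96, EGR1 by 3.82, TUBB2A by 3.16, SLC2A3 by 3.11, SLAMF7 by 2.75 and the drug efflux pump ABCB1 by 2.36 (adjusted p = 2.7e-05 for ABCB1). ANXA2, a calcium-dependent membrane-binding protein, rose 5.98-fold, to 7.97 ± 0.45 (SD, n = 3), and its pseudogene ANXA2P2 rose by 2.50, a probe set that can share signal with ANXA2. ZSWIM6 and CTTNBP2NL rose by 2.72 and 2.48.

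Of the 23 B cell identity genes, 9 fell at 8 h and 1 rose, the kinase gene LYN (15 fell and 1 rose adjusted over the list alone). The list median was -0.83 (adjusted p = 0.184 with an estimated correlation). Of the 24 MYC targets and ribosome biogenesis genes, 3 fell, MYC (-1.50), DKC1 and WDR43 (6 adjusted over the list alone; adjusted p = 0.301 with an estimated correlation). Autophagy and lysosome genes rose too, 6 of 22 at 8 h (6 adjusted over the list alone), with a median of 0.38 (adjusted p = 0.301 with an estimated correlation). DNAJB1, HSPA2 and BAG3 were the 3 of 20 heat shock proteins, chaperones and their partners, that rose at 8 h (3 adjusted over the list alone; adjusted p = 0.242 with an estimated correlation). RFX5, a transcription factor of MHC class II genes, fell by 1.11 at 8 h as the 1 of 14 in the list of MHC class II and antigen presentation, also adjusted over the list alone. Camera gave that list an adjusted p of 0.569 and no call. Camera called 11 lists at 8 h, 6 upward and 5 downward, and 0 held with an estimated correlation (adjusted p from 0.184 to 0.641).

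Limma called 1230 genes at 8 h against 0 h, 644 higher and 586 lower, with 285 and 281 at least 2-fold. The count was 759 without replicate 2 of 0 h, 575 in the fit of the 6 arrays alone and 2183 with array weights.

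Between 4 h and 8 h ANXA2 rose by 2.18 on the log2 scale (SE 0.34, adjusted p = 0.0119), ANXA2P2 by 1.98, the membrane glycoprotein GPNMB by 2.04, SERPINI1 by 1.75 and EXOC6B by 1.51. The death receptor FAS fell by 1.75 and BLNK, the linker of B cell receptor signalling, by 1.65, and RASSF6, ZNF75A and GCSAM fell too, with log2 differences of -1.84, -1.70 and -1.64. BLNK was the 1 of 23 B cell identity genes that fell in this interval (8 adjusted over the list alone; list adjusted p = 0.208 with an estimated correlation). Limma called 41 genes, 22 higher and 19 lower, with 28 at least 2-fold, and camera called 5 lists, of which 0 held with an estimated correlation (adjusted p from 0.208 to 0.769). The count was 8 without replicate 1 of 4 h, 0 without replicate 2 of 4 h and 0 without replicate 1 of 8 h. It was 0 in the fit of the 6 arrays, 20 with all probe sets tested singly, 68 with quantile normalization, 90 with the interquartile range as a covariate and 1039 with array weights. Each of the 10 genes named here lost its call without replicate 2 of 4 h (adjusted p from 0.0789 to 0.119). The share of higher genes was 53.7% as deposited and 71.4% with each array centred on its median.

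At 12 h ANXA2 was 13.4-fold above 0 h, at 9.13 ± 0.14 against 5.39 ± 0.65 (SD, n = 3 each, adjusted p = 3.22e-06). SPP1, the secreted phosphoprotein osteopontin, rose 11.3-fold, and TNFRSF9, a co-stimulatory receptor, rose by 3.11 on the log2 scale. EGR1 was higher by 3.86, SLC2A3 by 3.48, TUBB2A by 3.44, CCR7 by 3.38, ZSWIM6 by 3.02, ANXA2P2 by 3.00 and FILIP1 by 2.91. CR2 fell by 3.06 and RASGRP3, an exchange factor that responds to diacylglycerol and phorbol esters, fell by 2.93, from 9.33 ± 0.16 to 6.40 ± 0.45 (SD, n = 3 each, adjusted p = 3.68e-06). CLEC2D fell by 2.98 (adjusted p = 4.23e-07), RASSF6 by 3.31, the chitinase-like gene CHI3L2 by 3.14, GCSAM by 2.91, CLECL1 by 2.79, ACKR4 by 2.72, CD84 by 2.71 and RHOH by 2.70.

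At 12 h 13 of 23 B cell identity genes fell and LYN rose (16 fell and 2 rose adjusted over the list alone). The list median was then -1.05 (adjusted p = 0.119 with an estimated correlation). BTK, the kinase downstream of the B cell receptor, fell by 2.04 and IKZF3 by 2.36. In the autophagy and lysosome list 3 of 22 rose at 12 h, the lysosomal cholesterol transporter NPC1 by 2.73, SQSTM1 and ATP6V1H (9 adjusted over the list alone; adjusted p = 0.339 with an estimated correlation). Of the 24 genes of the unfolded protein and integrated stress response, 2 fell at 12 h, the serine synthesis gene PSAT1 by 1.02 and HSPA5 (2 adjusted over the list alone; adjusted p = 0.528 with an estimated correlation). Among p53 target genes, FAS fell by 2.08 at 12 h together with RRM2B and MDM2, and 2 of 20 rose, PLK3 and TNFRSF10B (5 fell and 3 rose adjusted over the list alone). Camera gave the p53 list an adjusted p of 0.414 and no call. The elongase gene ELOVL6 fell by 1.63 as the 1 of 12 in the list of fatty acid synthesis at 12 h, also adjusted over the list alone (camera adjusted p = 0.271, not called). ELOVL5 differed by -0.34 at 48 h (adjusted p = 0.174). Camera called 11 lists at 12 h, 5 upward and 6 downward, and 0 held with an estimated correlation (adjusted p from 0.119 to 0.528).

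Limma called 1483 genes at 12 h against 0 h, 720 higher and 763 lower, with 315 and 382 at least 2-fold. The count was 977 without replicate 2 of 0 h and 888 without replicate 1 of 12 h. The share of higher genes was 48.6% as deposited and 33.9% with each array centred on its median. At 12 h PSAT1 lost its call without replicate 3 of 0 h (adjusted p = 0.134) and DNAJB1 without replicate 2 of 0 h (adjusted p = 0.0656). Under 5 of 15 alternatives PSAT1 lost its call, and under 1 DNAJB1. Between 8 h and 12 h limma called 0 genes, with 1221 genes at an unadjusted p under 0.05, and 142 genes were called with array weights. Camera called 6 lists in this interval, 1 upward and 5 downward, none of which held with an estimated correlation (adjusted p from 0.618 to 0.769).

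**Figure D2:**
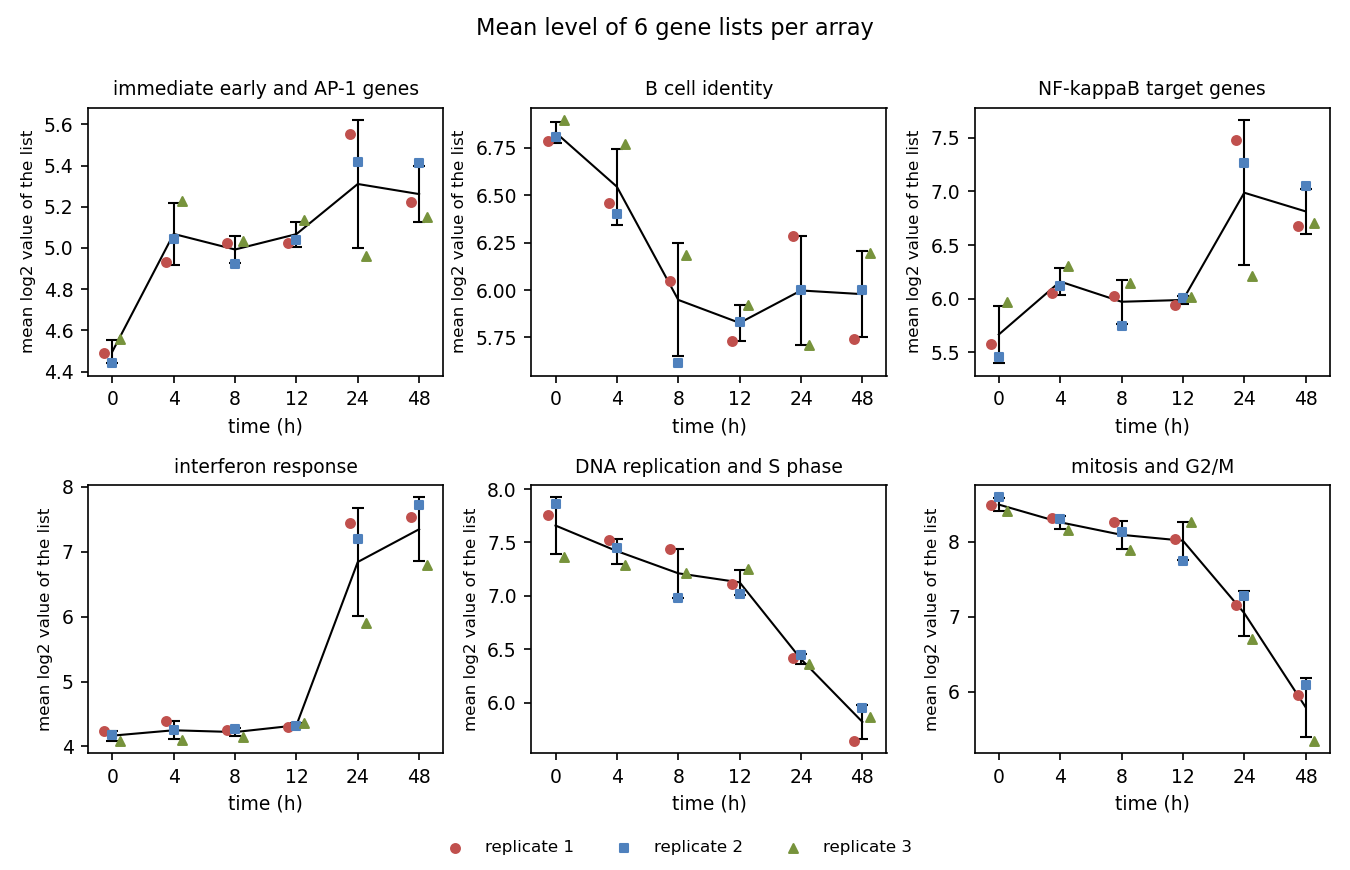
Mean log2 value of the measured members of 6 gene lists on each array, with 1 marker shape per replicate number, the line joining group means and the bars showing ± SD (n = 3), at harvest times spaced evenly on the axis. The interferon response list lies between 4.09 and 4.39 on all arrays of 0 h to 12 h and between 5.90 and 7.72 on all arrays of 24 h and 48 h, while the mitosis list falls from 8.49 at 0 h to 5.79 at 48 h.

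At 24 h IFIT1, an interferon-stimulated gene whose product binds viral RNA, was 116-fold above 0 h, at 10.10 ± 1.04 against 3.24 ± 0.57 (SD, n = 3 each, adjusted p = 2.12e-08). Its 0 h mean was little above the lower quartiles of the 0 h arrays, so the fold can be too small. IFI44L and IFI44, whose 0 h means of 2.79 and 2.63 lay below the lower quartile of each 0 h array (2.99 to 3.12), near background, rose by at least 5.98 and 5.42 on the log2 scale. IFIT3 rose by 5.48, the RNA sensor RIGI by 5.18, the cytidine deaminase APOBEC3B by 5.02, IFIT2 by 4.94, SAMD9L by 4.83 and SLFN5 by 4.72. TIMP1, an inhibitor of matrix metalloproteinases, rose 47.6-fold, to 9.95 ± 0.55 (SD, n = 3, adjusted p = 6.14e-08). The largest falls were RASSF6 by 3.38, the matrix protein gene SPARCL1 by 3.18, RGS13, a regulator of G protein signalling in germinal centre B cells, by 3.04, CADPS by 3.04, ACKR4 by 2.92, CR2 by 2.62 and BLNK by 2.58. The PCNA partner PCLAF fell by 2.77, the spindle checkpoint gene MAD2L1 by 2.73 and the nuclease-helicase DNA2 by 2.60.

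In the interferon response list, 17 of 25 members rose at 24 h against 0 h (20 adjusted over the list alone), with a median of 2.66 (adjusted p = 0.119 with an estimated correlation), while 0 of 25 passed at 4, 8 or 12 h. Replicate 3 of 24 h lay lower than the other 2, with a list mean of 5.90 against 7.44 and 7.19. Of the 31 DNA replication and S phase genes, 26 fell (26 adjusted over the list alone), with a median of -1.24 (adjusted p = 0.0395 with an estimated correlation). Of the 27 mitosis and G2/M genes, 25 fell (27 adjusted over the list alone), with a median of -1.30 (adjusted p = 0.0877 with an estimated correlation). Immediate early and AP-1 genes were also higher at 24 h, 11 of 24 (13 adjusted over the list alone; adjusted p = 0.22 with an estimated correlation). The list mean was 4.96 on replicate 3 of 24 h, against 5.55 and 5.42. EGR1 rose by 4.07, the AP-1 component FOS by 2.19 and the phosphatases DUSP1 and DUSP5 by 2.19 and 2.16.

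Among NF-kappaB target genes 13 of 22 rose at 24 h (16 adjusted over the list alone), with a median of 1.14 (adjusted p = 0.249 with an estimated correlation). On replicate 3 of 24 h their mean was 6.22, inside the 5.45 to 6.30 of the arrays of 0 h to 12 h, against 7.48 and 7.27 on the other 2. The interferon regulatory factors IRF1 and IRF4 rose by 2.79 and 2.37, with an SD of 1.73 for IRF1 at 24 h. Of the 28 chemokines, cytokines and their receptors, 14 rose and CXCR4 fell (15 rose and 1 fell adjusted over the list alone; adjusted p = 0.0877 with an estimated correlation). Their mean was 5.59 on replicate 3 of 24 h, against 6.64 and 6.37. TNFRSF9 rose by 4.70. Among NRF2 and antioxidant genes 8 of 20 rose and TXN fell (9 and 1 adjusted over the list alone; adjusted p = 0.243 with an estimated correlation). SRXN1, which repairs oxidized peroxiredoxins, rose by 2.37, the glutathione synthesis gene GCLC by 1.12 and TXNRD1 by 0.91. Within phorbol ester and protein kinase C signalling, 8 of 22 genes rose at 24 h and 3 fell, the exchange factors RASGRP1, RASGRP2 and RASGRP3 (11 rose and 3 fell adjusted over the list alone; adjusted p = 0.301 with an estimated correlation). The autophagy receptor SQSTM1 was higher by 2.99. The autophagy and lysosome list had 3 of 22 members higher at 24 h, SQSTM1, NPC1 and ATP6V1H (3 adjusted over the list alone; adjusted p = 0.334 with an estimated correlation).

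Among genes associated with histone deacetylase inhibition, 4 of 13 rose at 24 h, MT2A, H2BC5, CDKN1A and GSN, and STMN1 fell (5 and 1 adjusted over the list alone; adjusted p = 0.339 with an estimated correlation). Their mean was 6.22 on replicate 3 of 24 h, inside the 6.02 to 6.39 of the arrays of 0 h to 12 h, against 7.05 and 6.97 on the other 2. MT2A, a metal-binding metallothionein, rose by 2.60 and H2BC5 by 1.41. Of the 16 genes of cell cycle inhibition and growth arrest, 4 rose, GADD45B by 1.92, KLF6 by 1.79, the cyclin-dependent kinase inhibitor CDKN1A by 1.31 and CDKN2B (6 adjusted over the list alone; adjusted p = 0.446 with an estimated correlation). Their mean was 6.30 on replicate 3 of 24 h, inside the 5.96 to 6.77 of the arrays of 0 h to 12 h, against 6.79 and 6.80. Of the 18 cholesterol synthesis and uptake genes, 4 rose, INSIG1 by 1.49, HMGCS1 by 1.10, STARD4 by 1.04 and TM7SF2, and ACAT2 fell (5 rose and 1 fell adjusted over the list alone). Camera gave the cholesterol list an adjusted p of 0.108 and no call. Among 20 heat shock proteins HSPA1L, near background at 0 h (2.99), rose by at least 1.45, BAG3 by 1.41 and HSPA2 also, while HSPE1 and HSPD1 fell (4 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.601, not called). DNAJB1 and HSPA2 had been higher by 1.54 and 1.47 at 12 h. The stress-induced transcription factor DDIT3 rose by 2.52 from a 0 h level with an SD of 1.51. In its unfolded protein list 4 of 24 fell, MANF by 1.26, HSPA5, PDIA6 and PDIA4 (3 rose and 8 fell adjusted over the list alone; camera adjusted p = 0.114, not called). TNFRSF10B, a death receptor gene among the p53 targets, rose by 1.72 at 24 h. The proapoptotic gene BAK1 rose by 1.73.

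Limma called 2298 genes at 24 h against 0 h, 1241 higher and 1057 lower, with 641 and 503 at least 2-fold. Camera called 15 lists, 10 upward and 5 downward. DNA replication and S phase alone held with an estimated correlation, the others having an adjusted p from 0.0877 to 0.446. GADD45B and CDKN1A lost their calls at 24 h without replicate 1 of 24 h (adjusted p = 0.0542 and 0.0521), and H2BC5 and ITGAM without replicate 2 of 24 h (adjusted p = 0.149 and 0.0698). Of 15 alternatives H2BC5 lost its call under 6, ITGAM under 3, GADD45B under 2 and CDKN1A under 1.

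Between 12 h and 24 h IFIT1 rose by 6.27 on the log2 scale (SE 0.40, adjusted p = 1.87e-07), IFIT3 by 5.02, and IFI44L and IFI44, again near background at 12 h (2.68 and 2.59), by at least 6.09 and 5.46. CXCL10, a chemokine induced by interferon, rose 75-fold, from 4.15 ± 0.11 to 10.38 ± 1.07 (SD, n = 3 each, adjusted p = 1.8e-05). The DNA repair nuclease EXO1 fell by 1.99, and DNA2 (-1.72), the centrosomal kinase NEK2 (-1.69), the apoptosis inhibitor and mitotic regulator BIRC5 (-1.68) and the spindle gene SPAG5 (-1.67) fell too. In the interferon response list 16 of 25 rose in this interval (17 adjusted over the list alone), with a median of 2.26 (adjusted p = 0.0399 with an estimated correlation). Of the mitosis list 10 of 27 fell (24 adjusted over the list alone; adjusted p = 0.0739 with an estimated correlation). Of the DNA replication list 7 of 31 fell (19 adjusted over the list alone; adjusted p = 0.0739 with an estimated correlation). NF-kappaB target genes had 5 of 22 members higher, IRF1, BCL2A1, PLEK, NFKBIA and CFLAR (13 adjusted over the list alone; adjusted p = 0.208 with an estimated correlation).

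Limma called 252 genes between 12 h and 24 h, 150 higher and 102 lower, with 120 and 66 at least 2-fold. Camera called 11 lists, 8 upward and 3 downward, of which the interferon list alone held with an estimated correlation, the others having an adjusted p from 0.0739 to 0.618. The count was 114, 153 and 135 without replicates 1, 2 and 3 of 12 h in turn, 105 and 148 without replicates 1 and 2 of 24 h, and 1099 with array weights. EXO1 and NEK2 lost their calls without replicate 1 of 12 h (adjusted p = 0.0512 and 0.138). NEK2 lost its call under 4 of 15 alternatives and EXO1 under 1. The share of higher genes was 59.5% as deposited and 72.4% with each array centred on its median.

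At 48 h IFI44L was at least 196-fold above 0 h, at 10.41 ± 0.23 against 2.79 ± 0.22 (SD, n = 3 each, adjusted p = 4.01e-09). IFIT1 rose by 6.89 on the log2 scale, IFI44 by at least 6.64, the antiviral enzyme RSAD2 by at least 5.75, XAF1 by 5.61, the helicase gene DDX60 by at least 5.56, IFIT3 by 5.45 and SLFN5 by 5.15. The guanylate-binding protein gene GBP5 rose by 5.97 and the chemokine gene CXCL9 by 5.55, with SDs of 3.08 and 2.72 among the 3 arrays of 48 h (adjusted p = 0.00271 and 0.00376). The 0 h means of IFI44L, IFI44, DDX60 and GBP5, at 2.53 to 2.82, lay below the lower quartile of each 0 h array (2.99 to 3.12), and that of RSAD2, at 3.02, within this range. These levels were near background, so the 5 differences can be too small and give no order. The spread between arrays applies to them as well, with GBP5 at 5.235 on replicate 3 of 48 h. PCLAF, a partner of the replication clamp, fell 17.8-fold, from 8.46 ± 0.30 to 4.30 ± 0.61 (SD, n = 3 each, adjusted p = 1.03e-07). A second, dimmer BIRC5 probe set differed by -1.46 at 48 h, and a second, dimmer PCLAF probe set by -0.75 at 24 h, where the one used differed by -2.77. The mitotic kinase PBK fell by 4.10, BIRC5 by 3.90, PLK4, the kinase of centriole duplication, by 3.66, the kinesins KIF20A and KIF15 by 3.56 and 3.49, MAD2L1 by 3.47, SPARCL1 by 3.47, DEPDC1 by 3.41 and the cyclin CCNB2 by 3.39.

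All 27 measured members of the mitosis and G2/M list fell at 48 h (27 adjusted over the list alone), with a median of -2.82 (adjusted p = 0.0239 with an estimated correlation). CCNB1, the cyclin that drives entry into mitosis, fell by 3.37. In the DNA replication list 28 of 31 fell (28 adjusted over the list alone), with a median of -1.81 (adjusted p = 0.0239 with an estimated correlation). The replication factor RFC3 fell by 3.12, the helicase component CDC45 by 3.08, the thymidylate synthase gene TYMS by 2.97 and MCM10 by 2.95. Of the 25 replication-dependent histones, made for packaging new DNA, 10 fell (14 fell and 1 rose adjusted over the list alone; adjusted p = 0.339 with an estimated correlation). Among them H2BC14 fell by 3.10, H2AC21 by 2.78, H3C2 by 2.57 and H4C2 by 2.46. MYC targets and ribosome biogenesis genes fell in 6 of 24 cases at 48 h (12 adjusted over the list alone; adjusted p = 0.242 with an estimated correlation). UTP20 differed by -1.82, POLR1B by -1.23 and the spermidine synthase gene SRM by -1.14.

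In the interferon response list 23 of 25 rose at 48 h (25 adjusted over the list alone), with a median of 2.44 (adjusted p = 0.0877 with an estimated correlation). The list mean was 6.79 on replicate 3 of 48 h, against 7.53 and 7.72 on the other 2. The 2 members that did not pass, named after their values were seen, were MX1 with a difference of 0.44 (adjusted p = 0.0694) and IRF7 with 0.40 (adjusted p = 0.0989). The MX1 probe set stayed low at all times, at 3.23 to 3.81, and whether it measures MX1 was not tested. Chemokines, cytokines and their receptors rose in 13 of 28 cases (14 adjusted over the list alone; adjusted p = 0.135 with an estimated correlation), with the T cell chemokine CCL5 higher by 5.01 and CXCL10 by 4.28. Their mean was 5.82 on replicate 3 of 48 h, against 6.32 on each of the other 2. Among NF-kappaB target genes 11 of 22 rose (15 adjusted over the list alone; adjusted p = 0.347 with an estimated correlation). The ubiquitin-editing inhibitor TNFAIP3 rose by 2.33. The survival gene BCL2A1 rose 10-fold, to 9.78 ± 0.06 (SD, n = 3, adjusted p = 6.75e-06), and BCL2 by 1.93. Of the BCL2 family and caspases 8 of 24 rose (10 adjusted over the list alone; adjusted p = 0.301 with an estimated correlation). Among genes associated with histone deacetylase inhibition 7 of 13 rose and STMN1 fell (8 and 1 adjusted over the list alone; adjusted p = 0.301 with an estimated correlation). Their mean was 6.53 on replicate 3 of 48 h, against 7.06 and 7.17. H2BC12 rose by 1.88 and MT1X by 1.56.

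**Figure D3:**
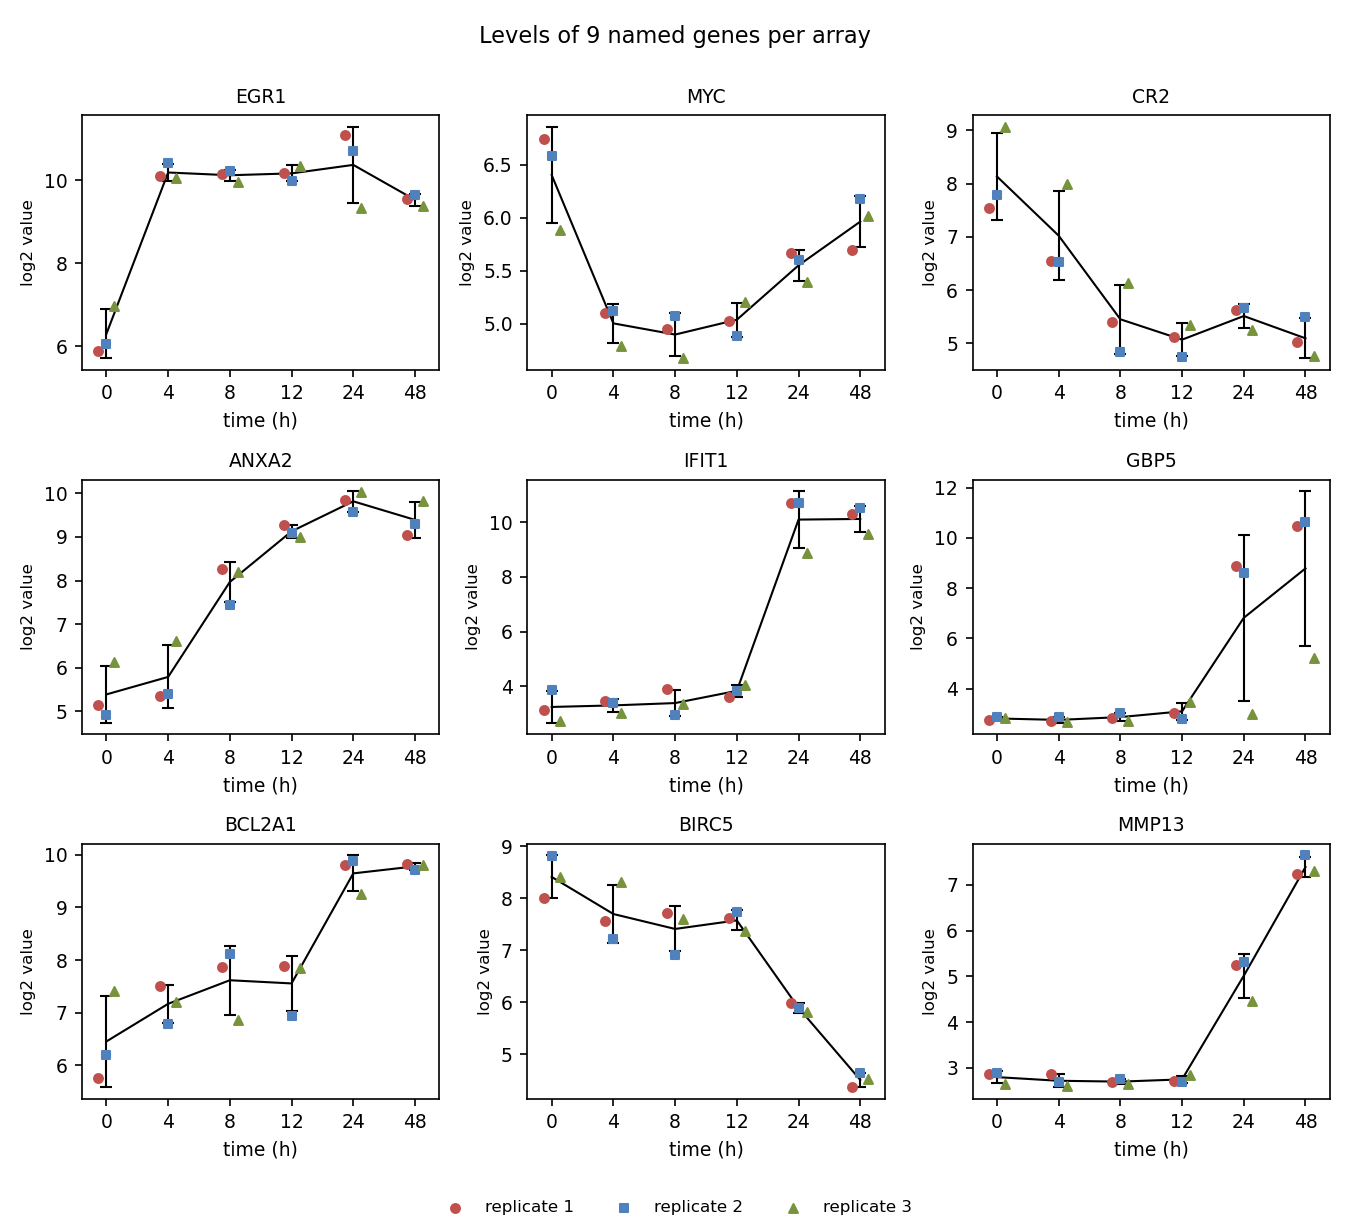
Log2 values of 9 named genes on each array, with 1 marker shape per replicate number, the line joining group means and the bars showing ± SD (n = 3), at harvest times spaced evenly on the axis. EGR1 moves from 6.30 at 0 h to 10.19 at 4 h, IFIT1 from 3.83 at 12 h to 10.10 at 24 h and MMP13 from 5.01 at 24 h to 7.39 at 48 h, while GBP5 has an SD of 3.08 at 48 h.

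Among plasma cell differentiation genes at 48 h, the joining chain gene JCHAIN (-2.87) and the co-stimulatory receptor CD27 (-2.41) fell with 4 others, while SLAMF7 rose by 3.28 and IRF4 also rose (6 fell and 3 rose of 17 adjusted over the list alone). Camera gave the plasma cell list an adjusted p of 0.34 and no call. Among p53 target genes, the ribonucleotide reductase subunit RRM2B (-1.95) and the repair gene DDB2 (-1.86) fell with FAS and MDM2, and 3 of 20 rose, TNFRSF10B, CDKN1A and PLK3 (5 fell and 4 rose adjusted over the list alone; camera adjusted p = 0.494, not called). Within prostaglandin and leukotriene synthesis, the prostaglandin receptor PTGER4 rose by 1.91 with PTGS1 and PTGES, and the lipoxygenase gene ALOX5 fell by 0.98 (4 rose and 1 fell of 14 adjusted over the list alone; camera adjusted p = 0.997, not called). PTGS1 had risen by 1.49 at 24 h. Of the MHC class II and antigen presentation genes, HLA-DMB rose by 1.26 and HLA-DQA1 by 1.18 with HLA-DQB1, 3 of 14 (4 adjusted over the list alone; camera adjusted p = 0.155, not called).

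Among 24 glycolysis and hypoxia genes 3 rose at 48 h, SLC2A3, ALDOC by 0.89 and the angiogenic factor VEGFA by 0.87, and PDK1 fell (3 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.564, not called). SLC2A3 had risen by 4.32 at 24 h, and DDIT4 differed there by 0.71 (adjusted p = 0.186; 0.0174 with array weights). Cell cycle inhibitors rose in 5 of 16 cases at 48 h, BTG1 by 1.53, GADD45B, KLF6, CDKN1A and CDKN2D, and CCNG1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.5 with an estimated correlation). The quinone reductase NQO1 rose by 1.66. Of its list of NRF2 and antioxidant genes 7 of 20 rose (9 rose and 2 fell adjusted over the list alone; adjusted p = 0.371 with an estimated correlation). The proton pump subunit ATP6V1H rose by 0.95. Of its autophagy and lysosome list 7 of 22 rose (9 adjusted over the list alone; adjusted p = 0.393 with an estimated correlation). BLNK fell by 2.99, and in the B cell identity list 9 of 23 fell and LYN rose at 48 h (14 and 1 adjusted over the list alone; adjusted p = 0.285 with an estimated correlation). The signalling inhibitors SPRED1 and SPRED2 rose by 1.90 and 1.85 and RASGRP1 fell by 1.68. In their phorbol ester list 5 of 22 rose and 2 fell at 48 h, RASGRP1 and RASGRP3 (6 and 3 adjusted over the list alone; camera adjusted p = 0.0905, not called). ASNS rose by 1.32 with DDIT3 in the unfolded protein list, and PDIA4 and PDIA6 fell (3 rose and 2 fell of 24 adjusted over the list alone; camera adjusted p = 0.63, not called). ACAT2 fell by 1.25 in the cholesterol list, where HMGCS1, INSIG1 and STARD4 rose (3 rose and 1 fell of 18 adjusted over the list alone; camera adjusted p = 0.606, not called).

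Limma called 2768 genes at 48 h against 0 h, 1275 higher and 1493 lower, with 625 and 763 at least 2-fold. Camera called 14 lists, 9 upward and 5 downward, of which the mitosis and DNA replication lists held with an estimated correlation and the others had an adjusted p from 0.0877 to 0.5. The share of higher genes was 46.1% as deposited and 33.1% with each array centred on its median, and ALDOC lost its call with that centring (adjusted p = 0.104). ALDOC and VEGFA lost their calls without replicate 3 of 48 h (adjusted p = 0.235 and 0.0569), ASNS without replicate 1 of 0 h (adjusted p = 0.0683) and MT1X without replicate 2 of 0 h (adjusted p = 0.121). Of 15 alternatives ALDOC lost its call under 7, MT1X under 5 and ASNS under 4. VEGFA also lost its call in the fit of only the 2 groups compared (adjusted p = 0.0578).

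Between 24 h and 48 h cell division genes fell further. CCNB1 fell by 2.36 on the log2 scale (SE 0.21, adjusted p = 1.38e-05), the spindle gene DLGAP5 by 2.12, and the kinesin KIF14 (-2.03), the centromere gene CENPW (-1.84) and the mitotic kinase AURKA (-1.77) fell too. MMP13, a collagenase, rose 5.2-fold, from 5.01 ± 0.48 to 7.39 ± 0.22 (SD, n = 3 each, adjusted p = 6.5e-06), and BCL2L11, a proapoptotic BCL2 family member, rose by 1.36. The ubiquitin-like ligase HERC5 rose by 1.95, SPATS2L by 1.77 and MEP1B by 3.59 (adjusted p = 0.049). MEP1B was near background at 24 h, at 2.80, below the lower quartile of each 24 h array, and had an SD of 2.73 at 48 h. In the mitosis list 14 of 27 fell in this interval (24 adjusted over the list alone), with a median of -1.34 (adjusted p = 0.0329 with an estimated correlation). In the DNA replication list 4 of 31 fell, MCM10, RFC3, RRM1 and CDC45 (15 adjusted over the list alone; adjusted p = 0.0739 with an estimated correlation). HERC5 was the 1 of 25 interferon response genes that rose (6 adjusted over the list alone; adjusted p = 0.685 with an estimated correlation).

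Limma called 74 genes between 24 h and 48 h, 13 higher and 61 lower, with 10 and 46 at least 2-fold. Camera called 5 lists, 2 upward and 3 downward, of which the mitosis list alone held with an estimated correlation, the others having an adjusted p from 0.0739 to 0.77. The count was 37 and 35 without replicates 1 and 2 of 24 h, 39, 45 and 258 without replicates 1, 2 and 3 of 48 h in turn. It was 10 in the fit of the 6 arrays alone, 37 with all probe sets tested singly and 206 with array weights. MEP1B, HERC5 and SPATS2L lost their calls without replicate 1 of 48 h (adjusted p = 0.267, 0.144 and 0.212). They also lost them without replicate 2 of 48 h, without any 1 replicate of 24 h and in the fit of the 6 arrays. MEP1B lost its call under 9 of 14 alternatives, quantile normalization among them (adjusted p = 0.0569). KIF14, CENPW and BCL2L11 lost theirs only in the fit of the 6 arrays (adjusted p = 0.0657, 0.0768 and 0.0667).

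Markers of other cell types stayed low, with list means between 3.23 and 3.73 in every group for the T cell, monocyte, epithelial, fibroblast and erythroid lists. Among T cell markers TRAT1 fell by 2.22 at 48 h as the 1 of 10 past the test (1 adjusted over the list alone; camera adjusted p = 0.601, not called), and CD3D rose by 1.57 at 24 h. Among monocyte and macrophage markers the integrin gene ITGAM rose by 0.85 at 24 h as the 1 of 11 (1 adjusted over the list alone; camera adjusted p = 0.356, not called), and CD14 differed by -0.25 at 8 h, where it was near background (adjusted p = 0.456). Of the 8 epithelial markers 0 passed at any time against 0 h, with KRT19 at 0.64 at 12 h (adjusted p = 0.0581; 1 adjusted over the list alone at 12 h) and KRT18 at 0.50 at 4 h (adjusted p = 0.276). Camera gave the epithelial list an adjusted p of 0.606 at 12 h and no call. KRT19 passed at 12 h with array weights (adjusted p = 0.0246), in the fit of the 6 arrays (0.0316), with the interquartile range as a covariate (0.0421) and with the dimmest genes left out (0.0467). Of the 9 fibroblast markers 0 passed, with THY1 at 0.34 (adjusted p = 0.216) and COL3A1 at 0.22 (adjusted p = 0.466) at 12 h. The fibroblast list was called downward between 12 h and 24 h with 0 members past the test (1 adjusted over the list alone; adjusted p = 0.241 with an estimated correlation). Of the 3 erythroid markers 0 passed, also adjusted over the list alone, with ALAS2 at 0.30 at 48 h (adjusted p = 0.316) and SLC4A1 at -0.22 at 24 h (adjusted p = 0.406). Camera gave the erythroid list an adjusted p of 0.655 at 48 h and no call.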

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

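The comparisons of effects between times and the counts over unused probe sets were planned, while the tests of the interferon rise, of an early harvest and of the butyrate response were chosen only after the results were seen. A difference between groups drew attention to 2 lists. The interferon response list had a median log2 difference of 2.26 at 24 h against 12 h (camera adjusted p = 0.0399 with an estimated correlation). The mitosis and G2/M list had a median of -1.34 at 48 h against 24 h (camera adjusted p = 0.0329 with an estimated correlation). A signal in data outside the main measurement drew attention to 2 sets of probe sets. Of the 1754 probe sets that name several genes, 65 were higher and 91 lower at 48 h than at 0 h in limma with an adjusted p under 0.05. Of the 12083 probe sets not named here, 161 were higher and 313 lower. Single arrays were not tested for deviation within the groups of 3. The estimated array weights were lowest for replicate 2 of 8 h (0.246) and replicate 3 of 24 h (0.402) and highest for replicate 1 of 8 h (5.184).

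The rise of the interferon response genes between 12 h and 24 h was weighed against 3 explanations. T cells, monocytes, epithelial cells, fibroblasts or erythroid cells mixed into the later cultures would raise their markers together, but the highest of the 5 list medians was -0.068 at 24 h against 12 h, which argues against these types and leaves others untested, while the single markers CD3D and ITGAM were higher at 24 h than at 0 h by 1.57 and 0.85. The scaling between arrays did not account for the rise either, since the lowest list median under quantile normalization or median centring was 2.30. Interferon beta made by the cultures themselves could not be decided. IFNB1, near background at 12 h (2.60), differed by 1.41 at 24 h against 12 h with an adjusted p of 0.0729, although it passed the F test (adjusted p = 0.0278). None of the other measured interferon genes passed in that comparison, with limma adjusted p from 0.416 for IFNW1 to 0.983 for IFNA6. Many of them lay near background, where a change can be hidden. IFNB1 was at 4.34, 4.85 and 2.85 on replicates 1 to 3 of 24 h, lowest on the array whose interferon list mean was lowest. At 48 h it was at 2.82, 3.40 and 2.86, lowest on replicate 1, whereas the interferon list mean was lowest on replicate 3.

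At 24 h and 48 h several interferon-inducible genes differed by over 10-fold between arrays of the same time, such as GBP5 at 8.87, 8.59 and 3.00 on replicates 1 to 3 of 24 h and CXCL9 at 11.06, 10.38 and 6.04 on those of 48 h. Of 7 genes over 10-fold apart at both times 6 were lowest on replicate 3, while RANBP3L was highest there. A compressed range of values on the arrays with low levels could not be decided, since 94 other risen genes kept a median of 77.5% of their group's mean rise on replicate 3 of 24 h and 94.3% at 48 h, against a bound of 80% at both times set before the test. That mean includes the array itself, so the percentages understate its distance from the others. Replicates 1 and 2 stood at 113% and 110% at 24 h and at 100% and 107% at 48 h. Cultures harvested earlier than labelled were argued against, because the mitosis list mean on these arrays lay below that of the other arrays, with a smaller gap of -0.448 over the 2 times. A weaker response of these cultures to butyrate predicted the smaller gap of -0.43 seen in the list of genes associated with histone deacetylase inhibition. The gap cannot single out that explanation, because other lists were low there and a compressed range could lower this list too. On replicate 3 the chemokine list mean was 5.59 at 24 h, against 6.64 and 6.37, and 5.82 at 48 h, against 6.32 on each other array. The NF-kappaB list was lowest there at 24 h (6.22 against 7.48 and 7.27) but not at 48 h. The full list of genes associated with histone deacetylase inhibition was not called against 0 h before 24 h.

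Mitochondrial respiratory chain genes, a family of 92 picked out after the data were seen, had medians below 0 at every later time, from -0.30 at 4 h to -0.48 at 48 h. With an estimated correlation the camera adjusted p was 0.0417 at 4, 12 and 48 h, 0.081 at 8 h and 0.0885 at 24 h. These values were adjusted only over families picked after the data were seen. They therefore carry no error rate and only describe the shift. Single genes fell in 1, 4, 14, 17 and 28 cases. An array-wide shift of short abundant transcripts, read from the ribosomal protein genes, could not be decided, since 58.1% of the median was kept at 4 h with the ribosomal mean as a covariate, and 83.2%, 63%, 67.4% and 75.7% at the later times. The scaling between arrays was argued against, with a median no nearer to 0 than -0.284 under quantile normalization or median centring.

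Chance was weighed by regrouping the arrays. Over 100 random splits of the 18 arrays into 6 groups of 3, the real one included, 1 split reached the 3023 genes of the F test, and the highest other count was 572, so a chance split of the arrays does not account for that count. For the lists between consecutive times, 50 of 100 splits reached the real 27 calls and the highest other count was 55. These splits can set arrays of distant times against each other, while the real comparisons hold neighbouring times only. The random splits therefore cannot decide whether chance gives this number. Splits of only the 6 arrays of neighbouring times were counted too, at the unadjusted p that the threshold against 0 h corresponds to. The highest other list counts were 6 against 6 for 8 h and 4 h and 8 against 6 for 12 h and 8 h. They were 15 against 11 for 24 h and 12 h and 12 against 5 for 48 h and 24 h. In no consecutive comparison did the real split exceed all others, so these camera calls were not shown to exceed chance. The 6 arrays of a comparison allow only 10 splits, too few to show a share under 0.05. Against 0 h only 1 of 10 splits, the real one, reached the gene count at each time, with highest other counts of 0 against 322 at 4 h, 3 against 1230 at 8 h, 0 against 1483 at 12 h, 2 against 2298 at 24 h and 0 against 2768 at 48 h. Between consecutive times the highest other counts were 4 against 41 for 8 h and 4 h, 0 against 252 for 24 h and 12 h and 8 against 74 for 48 h and 24 h, again reached by 1 of 10 splits. All 10 of 10 splits reached the 0 of 12 h against 8 h, where the highest other count was 1. For the lists against 0 h, 2 of 10 splits reached the 11 calls at 4 h, where the highest other count was 11, and 1 of 10 at the later times, with highest other counts of 9 against 11 at 8 h, 10 against 11 at 12 h, 14 against 15 at 24 h and 13 against 14 at 48 h.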

How the results depend on the processing

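The covariate for each array's interquartile range and the removal of replicate 2 of 8 h were chosen only after the data were seen. Of 220 results for named genes, 181 kept their direction and their side of the threshold under all alternatives, 37 lost their call under at least 1 of them and 0 turned direction. Of 89 list calls, 5 were kept under all alternatives, and 84 were lost with an estimated correlation, 43 with fry and 1 to 6 under each scaling, filter or weighting. The camera lists called fell to 0 at 4 h, 0 at 8 h, 0 at 12 h, 1 at 24 h, 2 at 48 h and 2 between consecutive times with an estimated correlation, and to 1 at 4 h, 6 at 8 h, 7 at 12 h and 7 between consecutive times with fry. With array weights the F test called 5422 genes, and limma called 566 at 4 h and 2183 at 8 h against 0 h, 1039 at 8 h against 4 h, 142 at 12 h against 8 h, 1099 at 24 h against 12 h and 206 at 48 h against 24 h. The weighted 8 h values rested mostly on replicate 1 of 8 h, with a weight of 5.184. In fits of only the 2 groups compared, which have fewer degrees of freedom, 125 genes were called at 4 h, 575 at 8 h, 0 at 8 h against 4 h and 10 at 48 h against 24 h. With the interquartile range as a covariate 526 were called at 4 h and 90 at 8 h against 4 h. With quantile normalization 68 were called at 8 h against 4 h, and with all probe sets tested singly 20 there and 37 at 48 h against 24 h. The other gene counts stayed within 1.5 times, and except for the smaller fits, the cause was not tested.

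Each comparison was fitted without each of its own arrays in turn and without replicate 2 of 8 h, the F test without each of the 18. This gave 2431 to 3240 genes for the F test, 109 to 417 at 4 h, 759 to 1004 at 8 h, 888 to 1733 at 12 h, 1634 to 2499 at 24 h and 2072 to 3050 at 48 h. Between consecutive times it gave 0 to 43 for 8 h against 4 h, 0 for 12 h against 8 h, 105 to 335 for 24 h against 12 h and 35 to 258 for 48 h against 24 h. Among these fits the highest counts against 0 h came without replicate 2 of 8 h, and 258 without replicate 3 of 48 h. It left 9 to 12 lists called at 4 h, 8 to 14 at 8 h, 9 to 12 at 12 h, 14 to 16 at 24 h, 13 to 15 at 48 h and 18 to 34 between consecutive times. Over these fits a call on a named gene was lost 117 times. In 1203 cases a named gene stayed on its side of the threshold, which includes genes that had no call. A list call was lost 63 times and kept 471 times.

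The replicate number was not taken to pair the arrays, since the labels name nothing that a number shares. A correlation over 0.1 was found for 20 of 45 same-number pairs (-0.243 to 0.6) and 25 of 90 different-number pairs. The mean correlation was 0.064 for the same number and -0.03 for different numbers. As a further hint of a pairing from the data, 15 of 18 arrays correlated best with an array of their own number, where 6 would by chance. With the number as a block, the counts were 3218 for the F test, 374, 1306, 1589, 2427 and 2897 at 4, 8, 12, 24 and 48 h, and 41, 0, 306 and 104 between consecutive times, with 28 consecutive lists. A pairing by number thus moved no count by over 1.5 times, and 1 list call and the call of GLA at 4 h were lost (adjusted p = 0.0535). Median centring moved the share of higher genes from 66.5% to 53.2% at 4 h, 48.6% to 33.9% at 12 h, 46.1% to 33.1% at 48 h, 53.7% to 71.4% at 8 h against 4 h and 59.5% to 72.4% at 24 h against 12 h. Genes near the background signal limit what arrays can show.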

Other observations

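The gene families and single genes of this part were chosen only after their values were seen. The adjusted p-values of the families, from camera, cover only the families picked. They carry no error rate, and a family called or not called by them is described, not tested. Of 6 APOBEC3 genes, cytidine deaminases that restrict viruses, 4 rose at 24 h and 4 at 48 h, with a median of 1.54 at 24 h and 1.71 at 48 h (adjusted p = 0.0417 at both with an estimated correlation), among them APOBEC3F by 2.34 and APOBEC3G by 1.87 at 24 h. Of 6 guanylate-binding protein genes, interferon-induced GTPases, 3 rose at 24 h, with a median of 1.57 (adjusted p = 0.096 with an estimated correlation), and 4 at 48 h, with a median of 2.04 (0.0885), among them GBP2 by 4.62 at 48 h. MX2, an antiviral GTPase gene, rose by 3.30 at 24 h and 5.04 at 48 h. LAMP3, a lysosomal membrane protein gene, rose by 2.41 at 24 h.

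Of 13 metallothionein genes, which bind zinc and copper, 4 rose at 24 h, with a median of 0.67 (adjusted p = 0.0885 with an estimated correlation), and 8 at 48 h, with a median of 0.70 (0.096), among them MT1G by 1.32 at 48 h. Of 17 annexins, calcium-dependent membrane-binding proteins, 6 rose at 24 h, with a median of 0.51 (adjusted p = 0.039 with an estimated correlation), among them ANXA5 by 1.11 and ANXA1, near background at 0 h, by at least 0.77. With an estimated correlation the annexin calls were lost at 12 h (median 0.13, 5 higher, adjusted p = 0.236) and at 48 h (median 0.38, 6 higher, adjusted p = 0.0885). Of 22 matrix metalloproteinases 4 rose at 48 h, with a median of 0.12 (adjusted p = 0.178 with an estimated correlation), among them the collagenase MMP13, near background at 0 h, by at least 4.60 and the matrilysin MMP7 by 1.77. Their inhibitor TIMP1 was higher by 2.82 at 12 h and 4.48 at 48 h. PTGS2, the inducible cyclooxygenase, differed by -0.18 at 48 h from a 0 h level of 3.09 (adjusted p = 0.468).

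Small nucleolar RNAs, which guide the modification of ribosomal RNA, had medians of -0.31, -0.11, -0.28, -0.34 and -0.24 at 4, 8, 12, 24 and 48 h over 175 genes, of which 29 fell at 24 h. With an estimated correlation their adjusted p was 0.039 at 4, 12 and 24 h, and the family was not called at 8 h (adjusted p = 0.474) or 48 h (adjusted p = 0.0885). Ribosomal protein genes had medians of -0.22, -0.15, -0.22, -0.20 and -0.24 over 96 genes (adjusted p from 0.209 to 0.665 with an estimated correlation). Proteasome genes had a median of -0.31 over 47 genes at 48 h, with 3 higher and 7 lower (adjusted p = 0.357 with an estimated correlation).

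The number of genes that differed by over 10-fold within a group was 1 at 0 h, 0 at 4 h, 1 at 8 h, 0 at 12 h, 15 at 24 h and 16 at 48 h. RANBP3L was at 2.80, 3.10 and 8.57 on replicates 1 to 3 of 24 h and at 3.26, 2.90 and 9.68 at 48 h, and the lens protein gene LGSN was at 3.59, 3.25 and 6.18 and at 3.24, 2.75 and 5.48. The list means for genes associated with histone deacetylase inhibition, without TXNIP, were 6.83, 6.74 and 6.13 at 24 h and 6.84, 6.90 and 6.41 at 48 h.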
